A study of Homo sapiens with 12 samples.

How the data were processed

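RNA was sequenced from HepG2 cells in 12 libraries, 3 each of vehicle (Control), 5 µM nobiletin (NOB), 2 µM sorafenib (SOR) and both (SOR+NOB). Per the labels, RNA was isolated with TRIzol, and the library protocol names poly(A) capture or rRNA removal without saying which. Per the submitters' processing notes, reads were aligned to GRCh38 with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3. The strand setting, the handling of reads that map more than once and any filters are not given in the sources used here. The deposited count table holds raw counts of 58735 genes, whose identifiers are all in GENCODE 29 and of which 58724 have the same start and end there. A deposited table holds FPKM of the same libraries, and the authors' group table holds FPKM averaged over the 3 libraries of a group. The FPKM of a gene equalled its count divided by gene length and library total, in FPKM units, times 1 factor per library of 0.939 to 1.08, to within 1e-06 of its value in all 20138 to 25014 genes with a count per library, and was 0 where the count was 0.

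Groups and replicate numbers were taken from the sample labels. The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 17115, and libraries were scaled by TMM. A robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 8.44%). The 6 comparisons were NOB, SOR and SOR+NOB against Control, SOR+NOB against SOR and against NOB, and the interaction, the effect of nobiletin with sorafenib minus its effect without. An F-test asked for any difference among the 4 groups. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and adjusted p under 0.05 was called. Fixed gene lists numbered 34, of which 32 had the 5 or more tested members needed, and were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists of a comparison). Camera calls numbered 21, 16, 12, 16, 16 and 13 in the order above, and 14, 8, 2, 11, 4 and 11 of them held with an estimated correlation. Shares of counts were compared by exact two-sided permutation of the libraries, which cannot give p below 0.1 with 3 against 3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

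The groups, tests, gene lists, alternatives other than the one named next and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls of each comparison among called protein-coding genes with a mean of at least 2 CPM over the compared libraries and, except for the interaction, no overlap of the libraries of the groups in CPM (chance gives 10% for 3 against 3). It also took up to 4 members with the smallest p in each called list and a fixed panel. Some genes that this rule took are not reported here. MT-ND4, MT-ND6, the mitochondrial tRNAs, XBP1 in NOB, LYZ and VIL1 were chosen after their values were seen. SLC39A10 is outside the rule too and was chosen after the rise of the metal response genes was seen, but before its own value was. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts (33593 genes), only the compared libraries in the fit and a replicate block. Others were limma on the authors' FPKM with pseudocounts of 1 and 0.1 (14934 genes with a mean FPKM of at least 0.5), protein-coding genes only (12871), a minimum mean of 5 CPM for the overlap, camera with an estimated correlation, fry, and leaving out each library. Removal of the GC and length trend was added after the data were seen.

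Replicate numbers might pair libraries across groups, so this was checked. Deviations from the group mean of libraries with the same number had a median correlation across genes of -0.01 over 18 pairs (-0.25 to 0.23), and only 3 of 12 libraries correlated best with a library of their own number. The numbers were therefore not used for pairing, and the replicate block stands as an alternative. No pair of libraries agreed within sampling noise. In a test on simulated data with 50 genes changed at each size, NOB against Control recovered 20% of changes of 1.25-fold, 54% of 1.5-fold, 68% of 2-fold and 98% of 4-fold, and called 7 of 16123 unchanged genes. Far fewer genes were changed there than the 38.2% called in NOB against Control, so these rates may not hold for the data. Precision depended on total counts, 17945656 to 25669823 per library, and on the spread between libraries. Counting intervals (95%) and floors (3 counts over the 3 libraries of a group) cover counting error only. The FPKM tables were used only as alternatives, and no sample was left out.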

Results

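RNA was sequenced from HepG2 cells, an established human liver cancer line, in 12 libraries that form 4 groups of 3. The groups received vehicle (Control), nobiletin at 5 µM (NOB), sorafenib at 2 µM (SOR) or both compounds at these doses (SOR+NOB). Nobiletin is a polymethoxylated flavonoid of citrus peel, and sorafenib is a kinase inhibitor used against liver cancer whose targets include RAF kinases and VEGF receptors. The time of exposure is not given in the labels used here. Total counts were 23120392, 21057154 and 21646622 in Control and 22741882, 20196645 and 23647659 in NOB. They were 25669823, 19202769 and 21544478 in SOR and 17945656, 22571151 and 21295554 in SOR+NOB. Levels below are CPM (counts scaled to the TMM-adjusted library size), mean ± SD with n = 3. The largest rises and falls named are among called protein-coding genes with a mean of at least 2 CPM over the compared libraries and no overlap of the groups in CPM. Positions are on GRCh38, and log2 fold changes (log2FC) are given ± SE from edgeR.

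Of 17115 genes tested, 13434 differed among the 4 groups (78.5%, edgeR quasi-likelihood F-test, adjusted p under 0.05). NOB differed from Control in 6536 genes, of which 536 rose and 816 fell by at least 2-fold. SOR differed from Control in 7020 genes, of which 758 rose and 952 fell by at least 2-fold. SOR+NOB differed from Control in 10981 genes, from SOR in 10785 and from NOB in 10387, and 8908 genes departed from the sum of the single log2 effects. The first principal component of log2 CPM held 46.8% of the variance and the next held 17.9%. SOR+NOB replicate 1 stood apart from its group: its counts differed from those of replicates 2 and 3 with a chi-square per degree of freedom of 27.6 and 19.2, against 2.78 to 5.58 for the other replicate pairs. It also had the lowest number of genes with a count, 20138, where the other libraries had 22542 to 25014.

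**Figure D1:**
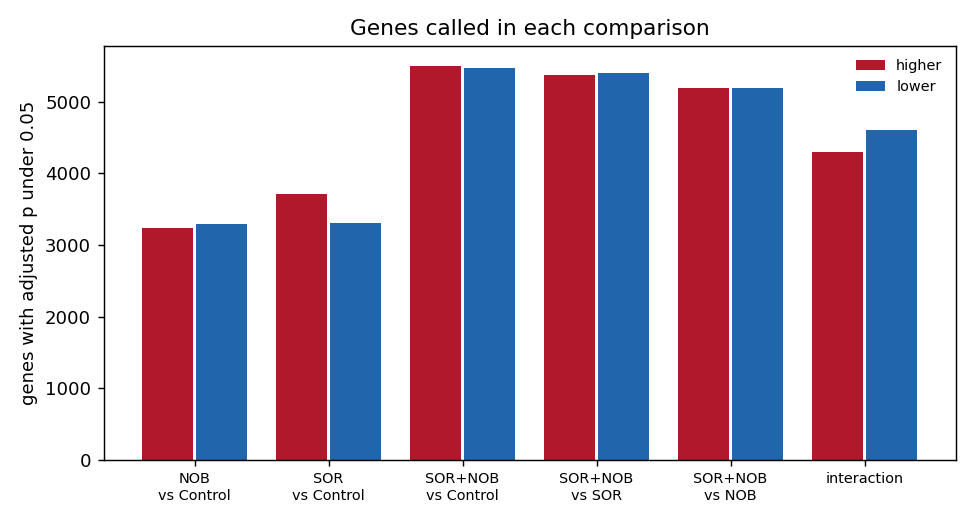
Bars give the number of genes with adjusted p under 0.05 (vertical axis, starting at 0) that were higher (red) or lower (blue) in each comparison, and for the interaction in the difference of effects. The 3 comparisons that involve SOR+NOB held 10981, 10785 and 10387 called genes, while NOB and SOR against Control held 6536 and 7020.

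In NOB against Control, which measures nobiletin alone, genes of cell division and of protein folding in the endoplasmic reticulum rose together, and genes for plasma proteins made by the liver fell. All 24 tested mitosis genes rose (24 adjusted over the list alone) with a median log2FC of 1.53 (camera, adjusted p = 9.66e-20). The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) went from 29.5 ± 2.29 to 88.0 ± 1.64 CPM, and TOP2A, which untangles DNA before chromosomes separate, rose by 1.82 ± 0.08 on the log2 scale. Of 24 DNA replication genes, 23 rose (23 adjusted over the list alone, median 1.01, adjusted p = 9.35e-15), among them the origin licensing factor CDC6 (2.5 ± 0.11), the ribonucleotide reductase subunit RRM2 (2.36) and the sliding clamp PCNA (0.97). Of 19 endoplasmic reticulum chaperone genes, 18 rose and 1, the transcription factor XBP1, fell (19 adjusted over the list alone, median 0.88, adjusted p = 1.36e-12). Their central chaperone HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) went from 1162 ± 33.9 to 2257 ± 12.8 CPM, and PDIA4, a disulfide isomerase, rose by 1.44 ± 0.05.

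Lipid synthesis genes also rose in NOB. Of 24 tested cholesterol genes 16 rose and 3 fell (20 adjusted over the list alone, median 0.43, camera adjusted p = 1.48e-05). Of 18 fatty acid and triglyceride synthesis genes 10 rose and 2 fell (12 adjusted over the list alone, median 0.29, adjusted p = 0.00139). SCD, which makes monounsaturated fatty acids (ENSG00000099194, chromosome 10, 100347124 to 100364834), rose by 1.21. The list of ATF4 stress response genes rose in 17 of 28 members and fell in 6 (25 adjusted over the list alone, median 0.36, adjusted p = 7.93e-04), with ALDH1L2 (2.01) and MTHFD2 (0.79) of mitochondrial folate metabolism among those that rose. That call was not kept with an estimated correlation between genes (adjusted p = 0.125 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 4 of 7 members and fell in 1 (5 adjusted over the list alone, median 0.44, adjusted p = 0.0129, and adjusted p = 0.0538 with an estimated correlation). Their best-known target CYP1A1, an enzyme that oxidises aromatic compounds (ENSG00000140465, chromosome 15, 74719542 to 74725610), went from 3.20 ± 0.769 to 29.6 ± 1.26 CPM, and NQO1 rose by 0.91. Glycolysis genes rose in 11 of 22 members and fell in 2 (14 adjusted over the list alone, median 0.16, adjusted p = 0.0129, and adjusted p = 0.143 with an estimated correlation), led by the glucose transporter SLC2A1 (1.23). Nuclear-encoded genes of oxidative phosphorylation rose in 17 of 28 and fell in 1 (18 adjusted over the list alone, median 0.20, adjusted p = 0.00287, and adjusted p = 0.173 with an estimated correlation). NRF2 targets rose in 11 of 23 and fell in 4 (16 adjusted over the list alone, median 0.23, adjusted p = 0.0296, and adjusted p = 0.303 with an estimated correlation), with HMOX1, which breaks down heme, at -2.92. Without Control replicate 2 the NRF2 call was lost (adjusted p = 0.0509). Metallothionein and metal response genes rose in 4 of 8 members (4 adjusted over the list alone, median 0.96, or 0.91 with MT1M, which has no counts in 1 group, at its bound, adjusted p = 0.00521).

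Hepatocyte secreted proteins fell in 18 of 24 genes with NOB and rose in 3 (22 adjusted over the list alone, median -0.58, camera adjusted p = 7.77e-09). Albumin (ALB, ENSG00000163631, chromosome 4, 73397114 to 73421412) went from 6428 ± 141 to 3094 ± 48.5 CPM, and the hemoglobin scavenger HP had a log2FC of -2.19. Core clock and clock output genes fell in 9 of 18 members and rose in 1 (11 adjusted over the list alone, median -0.48, adjusted p = 0.00399). Those that fell included PER3 (-1.33), PER2 (-0.81) and the nuclear receptors RORA (-0.81) and NR1D1 (-0.80), while ARNTL did not pass. Bile acid genes fell in 8 of 12 and rose in 2 (10 adjusted over the list alone, median -0.59, adjusted p = 0.00222), with BAAT, which conjugates bile acids, at -2.39. Interferon response genes fell in 10 of 16 and rose in 2 (12 adjusted over the list alone, median -0.88, adjusted p = 0.00103). Matrix and epithelial-mesenchymal genes fell in 10 of 15 and rose in 2 (12 adjusted over the list alone, median -0.48, adjusted p = 9.94e-04), fibronectin (FN1) at -1.10. Heat shock genes fell in 11 of 16 and rose in 1 (13 adjusted over the list alone, median -0.36, adjusted p = 1.18e-04), with HSPB1 at -2.02. Autophagy and lysosome genes fell in 11 of 23 and rose in 2 (13 adjusted over the list alone, median -0.22, adjusted p = 0.00983). Liver cancer and oncofetal markers fell in 13 of 17 and rose in 3 (16 adjusted over the list alone, median -0.49, adjusted p = 2.80e-04), with the fetal plasma protein AFP at -0.86 and the glutamine synthetase GLUL at -1.05. NF-kB and acute inflammation genes fell in 7 of 14 and rose in 1 (8 adjusted over the list alone, median -0.39, adjusted p = 0.0129, and adjusted p = 0.111 with an estimated correlation). Gluconeogenesis genes fell in 6 of 10 and rose in 3 (9 adjusted over the list alone, median -0.55, adjusted p = 0.0356, and adjusted p = 0.0909 with an estimated correlation). Without NOB replicate 1 the gluconeogenesis call was lost (adjusted p = 0.0503). The genes with the largest rises in NOB were AGR2, a disulfide isomerase of secretory cells (ENSG00000106541, chromosome 7, 16791811 to 16833433; 1.7 ± 0.621 to 20.7 ± 2.42 CPM, log2FC 3.6 ± 0.24), then CYP1A1 (3.20) and MT1G (2.84). The largest falls were those of ACSM2A (-3.93), TRIM50 (-3.88) and ACSM2B (-3.82). ACSM2A and ACSM2B are near-identical neighbours, so the split of reads between them is uncertain.

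**Figure D2:**
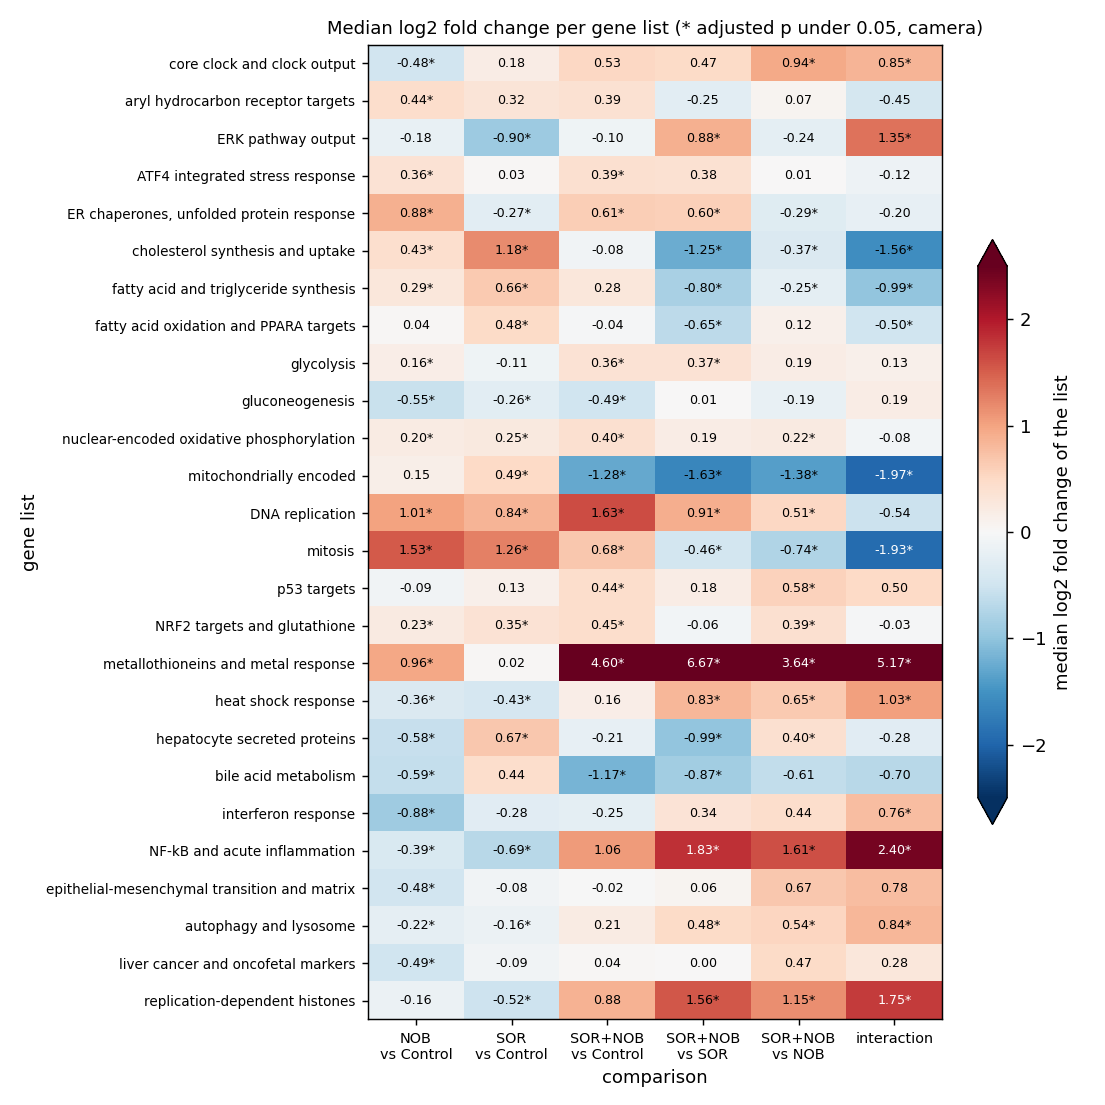
Colours and numbers give the median log2FC of each fixed gene list (vertical axis) in each comparison (horizontal axis), for the lists called at least once, and * marks camera adjusted p under 0.05; the colour scale ends before the largest medians. Mitosis was higher in NOB and SOR against Control (1.53 and 1.26) and had a negative interaction (-1.93), and the metal response list was higher in SOR+NOB in all 3 comparisons that involve it.

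In SOR against Control, which measures sorafenib alone, genes switched on by the ERK pathway fell, and genes of lipid synthesis and of cell division rose. Of 21 ERK output genes 18 fell and 1 rose (20 adjusted over the list alone, median -0.90, camera adjusted p = 5.74e-10). DUSP6, a phosphatase induced by ERK that acts back on it (ENSG00000139318, chromosome 12, 89347232 to 89353271), went from 114 ± 4.10 to 30.3 ± 0.483 CPM, and SPRY4, another feedback inhibitor, had a log2FC of -1.91 ± 0.07. Cholesterol synthesis and uptake genes rose in 22 of 24 members and fell in 1 (23 adjusted over the list alone, median 1.18, adjusted p = 3.04e-14). Fatty acid and triglyceride synthesis genes rose in 14 of 18 and fell in 2 (16 adjusted over the list alone, median 0.66, adjusted p = 3.54e-06), with DGAT1 at 2.09 and SCD at 1.79. Fatty acid oxidation genes rose in 15 of 20 and fell in 2 (19 adjusted over the list alone, median 0.48, adjusted p = 7.43e-06), EHHADH by 1.2 and the nuclear receptor PPARA by 0.98, while CPT1A, which admits fatty acids into mitochondria, fell (-1.80).

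All 24 mitosis genes rose in SOR (24 adjusted over the list alone, median 1.26, camera adjusted p = 3.55e-16), MKI67 to 68.2 ± 1.26 CPM. Of 24 DNA replication genes, 22 rose (22 adjusted over the list alone, median 0.84, adjusted p = 3.74e-11). Hepatocyte secreted proteins rose in 16 of 24 and fell in 7 (23 adjusted over the list alone, median 0.67, adjusted p = 6.35e-05, and adjusted p = 0.125 with an estimated correlation). ALB was at 21066 ± 597 CPM against 6428 ± 141 in Control and the iron carrier TF at a log2FC of 2.35. Mitochondrially encoded mRNAs rose in 11 of 13 (11 adjusted over the list alone, median 0.49, adjusted p = 7.04e-04, and adjusted p = 0.386 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 19 of 28 (21 adjusted over the list alone, median 0.25, adjusted p = 3.95e-05, and adjusted p = 0.105 with an estimated correlation). NRF2 targets rose in 15 of 23 and fell in 2 (17 adjusted over the list alone, median 0.35, adjusted p = 4.02e-04, and adjusted p = 0.148 with an estimated correlation). Heat shock genes fell in 12 of 16 and rose in 2 (15 adjusted over the list alone, median -0.43, adjusted p = 1.14e-04), HSPB1 at -1.47. Autophagy and lysosome genes fell in 9 of 23 and rose in 2 (12 adjusted over the list alone, median -0.16, adjusted p = 0.00201), WIPI1 at -1.64. Endoplasmic reticulum chaperones fell in 12 of 19 and rose in 3 (16 adjusted over the list alone, median -0.27, adjusted p = 0.00527, and adjusted p = 0.0533 with an estimated correlation). NF-kB and acute inflammation genes fell in 9 of 14 and rose in 1 (10 adjusted over the list alone, median -0.69, adjusted p = 0.00332, and adjusted p = 0.0944 with an estimated correlation). The cytokine signalling inhibitor SOCS3 was at -3.82 and the adhesion molecule ICAM1 at -2.03. Gluconeogenesis genes fell in 5 of 10 and rose in 2 (8 adjusted over the list alone, median -0.26, adjusted p = 0.0373, and adjusted p = 0.105 with an estimated correlation). This call was also lost with the replicate number as a block (adjusted p = 0.0547). Histone genes fell in 5 of 8 (5 adjusted over the list alone, median -0.52, adjusted p = 0.0397, and adjusted p = 0.105 with an estimated correlation), a call lost with no filter on low counts (adjusted p = 0.0682). The largest rises belonged to PGLYRP2, a liver enzyme that cleaves peptidoglycan (ENSG00000161031, chromosome 19, 15468645 to 15498956; 0.140 ± 0.0967 to 16.1 ± 1.67 CPM), to the organic anion transporter SLC22A7 (2.69 ± 0.514 to 92.7 ± 2.86 CPM) and to the urea cycle enzyme OTC (log2FC 5.05). The largest falls belonged to MYO1G (-5.40), VGF (-5.07) and LFNG (-4.77). CYP7A1, the rate-limiting enzyme of bile acid synthesis (ENSG00000167910, chromosome 8, 58490178 to 58500236), rose from 1.7 ± 0.202 to 14.4 ± 1.73 CPM.

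The NOB and SOR effects were compared across genes. Both compounds raised 1564 genes and both lowered 1539, while 378 genes were higher in NOB and lower in SOR and 575 were lower in NOB and higher in SOR. Independent lists of these sizes would share 705, 635, 625 and 716, but the same 3 Control libraries enter both lists, so part of the excess in the same direction and of the deficit in opposite directions may come from them. Unchanged groups that share controls gave 0 shared calls in 20 simulations (edgeR), which says nothing of lists with real effects. Across the 17115 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.41. These values share the Control libraries too, and the simulations gave a mean r of 0.50 (0.48 to 0.53), so r itself does not separate a shared response from shared controls. The covariance was 0.228, against a simulated mean of 0.0402. The slope of the SOR+NOB effect on the sum of the single effects was 0.393, against 0.335 (0.320 to 0.355) in the simulations. The Pearson r with that sum was 0.398, against a simulated mean of 0.579. The simulated groups had no effects, so their slope and r come from the shared controls and are no reference for additivity of real effects. Departure from additivity is tested gene by gene in the interaction.

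In SOR+NOB against Control, which measures both compounds together, genes of the metal response and of DNA replication rose. Metallothionein and metal response genes rose in 7 of 8 members (7 adjusted over the list alone, median 4.60, camera adjusted p = 4.23e-05). MT2A, which binds zinc and copper (ENSG00000125148, chromosome 16, 56608199 to 56609497), went from 31.7 ± 3.0 to 562 ± 25.3 CPM and MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065) from 0.944 ± 0.265 to 292 ± 7.84 CPM. The zinc exporter SLC30A1 rose by 1.23 ± 0.06 on the log2 scale. Reads of near-identical metallothionein copies were not resolved here, so values of single MT1 genes are uncertain. The zinc transporter SLC30A2 (ENSG00000158014, chromosome 1, 26037252 to 26046133) had 498 counts in SOR+NOB and 0 in the other groups, at least 171-fold higher than Control with a floor of 3 counts over the group. HAMP, the iron hormone hepcidin (ENSG00000105697, chromosome 19, 35280716 to 35285143), went from 4.02 ± 0.653 to 113 ± 18.1 CPM. Of 24 DNA replication genes, 22 rose (22 adjusted over the list alone, median 1.63, adjusted p = 4.84e-10), among them CDC6 (3.03 ± 0.11), RRM1 (1.87), MCM4 (1.84) and MCM5 (1.64) of the replicative helicase and nucleotide supply.

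Mitochondrially encoded mRNAs fell in 12 of 13 genes with both compounds (12 adjusted over the list alone, median -1.28, camera adjusted p = 4.23e-05, and adjusted p = 0.294 with an estimated correlation). MT-ND4 was not called (-0.13, edgeR adjusted p = 0.465). MT-CO3, a subunit of cytochrome c oxidase, went from 6210 ± 393 to 1607 ± 48.8 CPM. As a share of all counts, mitochondrial mRNAs were 6.81% ± 0.309 in Control and 3.88% ± 0.698 in SOR+NOB. Mitochondrial rRNAs were 1.36% ± 0.0381 and 2.91% ± 0.180 (exact two-sided permutation p = 0.1 for both, the smallest p that 3 against 3 allows). Small nuclear and nucleolar RNAs, which lack a poly(A) tail, took 0.00867% ± 0.00115 of counts in Control and 0.0128% ± 0.00119 in SOR+NOB (exact permutation p = 0.1). Nuclear rRNA, also without a tail, had 48 counts in Control and 1387 in SOR+NOB (7.38e-05% ± 3.82e-05 and 0.00220% ± 5.97e-04 of counts, exact permutation p = 0.1). Mitochondrial tRNAs, which also lack a tail, were called lower in 16 of 17 genes. Of the 5 with at least 10 CPM in Control, 4 were at -2.75 to -1.88, and MT-TP was not called (0.08, edgeR adjusted p = 0.484) but was called higher without SOR+NOB replicate 2 (0.20, adjusted p = 0.0461, where RLE scaling and leaving out each compared library gave 0.0461 to 0.906). The mitochondrial list stood at -0.96 relative to the Control mean in SOR+NOB replicate 1 and -1.46 and -1.45 in replicates 2 and 3 (medians, log2). Nuclear-encoded oxidative phosphorylation genes rose in 21 of 28 and fell in 1 (22 adjusted over the list alone, median 0.40, adjusted p = 2.68e-04, and adjusted p = 0.233 with an estimated correlation), SDHB by 1.24.

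**Figure D3:**
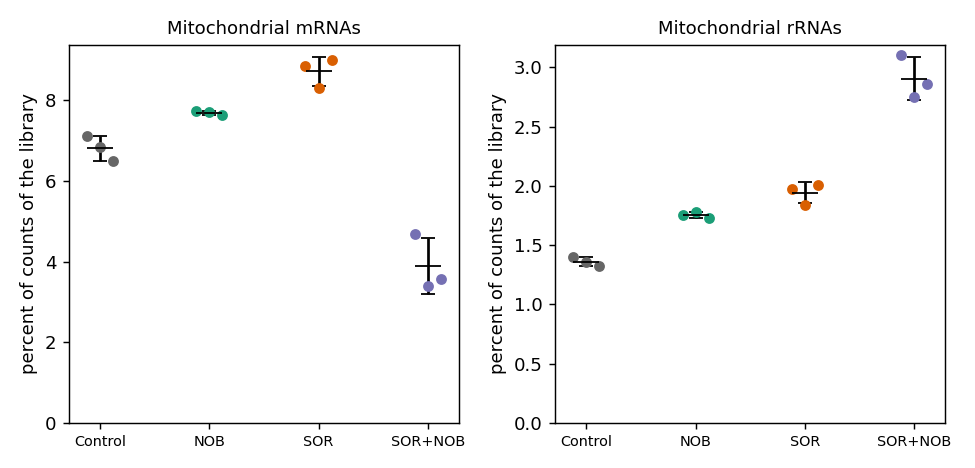
Points are the 3 libraries of each group, horizontal lines the group means and bars the SD; the vertical axes give the percent of each library's counts in mitochondrially encoded mRNAs (left) and rRNAs (right) and start at 0. SOR+NOB lies below every other library for the mRNAs and above every other library for the rRNAs.

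Mitosis genes rose in 18 of 24 with both compounds and fell in 2 (21 adjusted over the list alone, median 0.68, camera adjusted p = 1.54e-04, and adjusted p = 0.141 with an estimated correlation). CCNA2, a cyclin of S phase and early mitosis, rose by 1.80, while MKI67 was at 32.2 ± 2.66 CPM and did not pass (0.12 ± 0.08). Bile acid genes fell in 9 of 12 and rose in 1 (10 adjusted over the list alone, median -1.17, adjusted p = 0.00849, and adjusted p = 0.141 with an estimated correlation). CYP7A1 had 0 counts in SOR+NOB and 111 in Control, at least 35.9-fold lower, and the repressor of bile acid synthesis NR0B2 had a log2FC of -1.76. ATF4 stress response genes rose in 16 of 28 and fell in 8 (24 adjusted over the list alone, median 0.39, adjusted p = 0.0359, and adjusted p = 0.339 with an estimated correlation). The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) went from 514 ± 10.5 to 1970 ± 168 CPM and ATF3 rose by 1.97, while the cystine carrier SLC7A11 fell (-1.77). Endoplasmic reticulum chaperones rose in 13 of 19 and fell in 3 (16 adjusted over the list alone, median 0.61, adjusted p = 0.00449, and adjusted p = 0.103 with an estimated correlation), HSPA5 by 0.74. Glycolysis genes rose in 14 of 22 and fell in 4 (18 adjusted over the list alone, median 0.36, adjusted p = 0.0421, and adjusted p = 0.268 with an estimated correlation), PKM by 1.01. Without SOR+NOB replicate 2 the glycolysis call was lost (adjusted p = 0.0523). Gluconeogenesis genes fell in 7 of 10 and rose in 2 (9 adjusted over the list alone, median -0.49, adjusted p = 0.0421, and adjusted p = 0.186 with an estimated correlation), IGFBP1 at -2.47. p53 targets rose in 14 of 21 and fell in 4 (18 adjusted over the list alone, median 0.44, adjusted p = 0.0234, and adjusted p = 0.268 with an estimated correlation), GADD45A by 2.22. NRF2 targets rose in 15 of 23 and fell in 5 (21 adjusted over the list alone, median 0.45, adjusted p = 0.0234, and adjusted p = 0.330 with an estimated correlation), while HMOX1 fell (-2.03).

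Several lists that passed with a single compound did not pass with both. Cholesterol genes gave 7 higher and 8 lower of 24 (15 adjusted over the list alone, median -0.08, camera adjusted p = 0.767). ERK output genes gave 8 higher and 9 lower of 21 (17 adjusted over the list alone, adjusted p = 0.513), DUSP6 at -1.68 and MYC at 1.07. Hepatocyte secreted proteins gave 7 higher and 13 lower of 24 (20 adjusted over the list alone, adjusted p = 0.137). All 18 clock genes were called, 11 higher and 7 lower (18 adjusted over the list alone, adjusted p = 0.112). Among them NR1D1, a repressor of the clock loop (ENSG00000126368, chromosome 17, 40092787 to 40100725), went from 25.6 ± 2.85 to 249 ± 2.32 CPM. Among the largest rises were also the histamine receptor HRH3 (710 against 3 counts, 244-fold, 95% counting interval 83.2 to 1187) and NEURL3 (6.48). DEPP1, an autophagy regulator induced by FOXO factors (ENSG00000165507, chromosome 10, 44970981 to 44978810), fell most among genes with a mean of at least 2 CPM over the compared libraries, from 338 ± 14.7 to 4.06 ± 0.832 CPM, followed by C1orf116 (-5.93) and F13B (-5.88). Without SOR+NOB replicate 1, 11392 genes were called in this comparison.

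**Figure D4:**
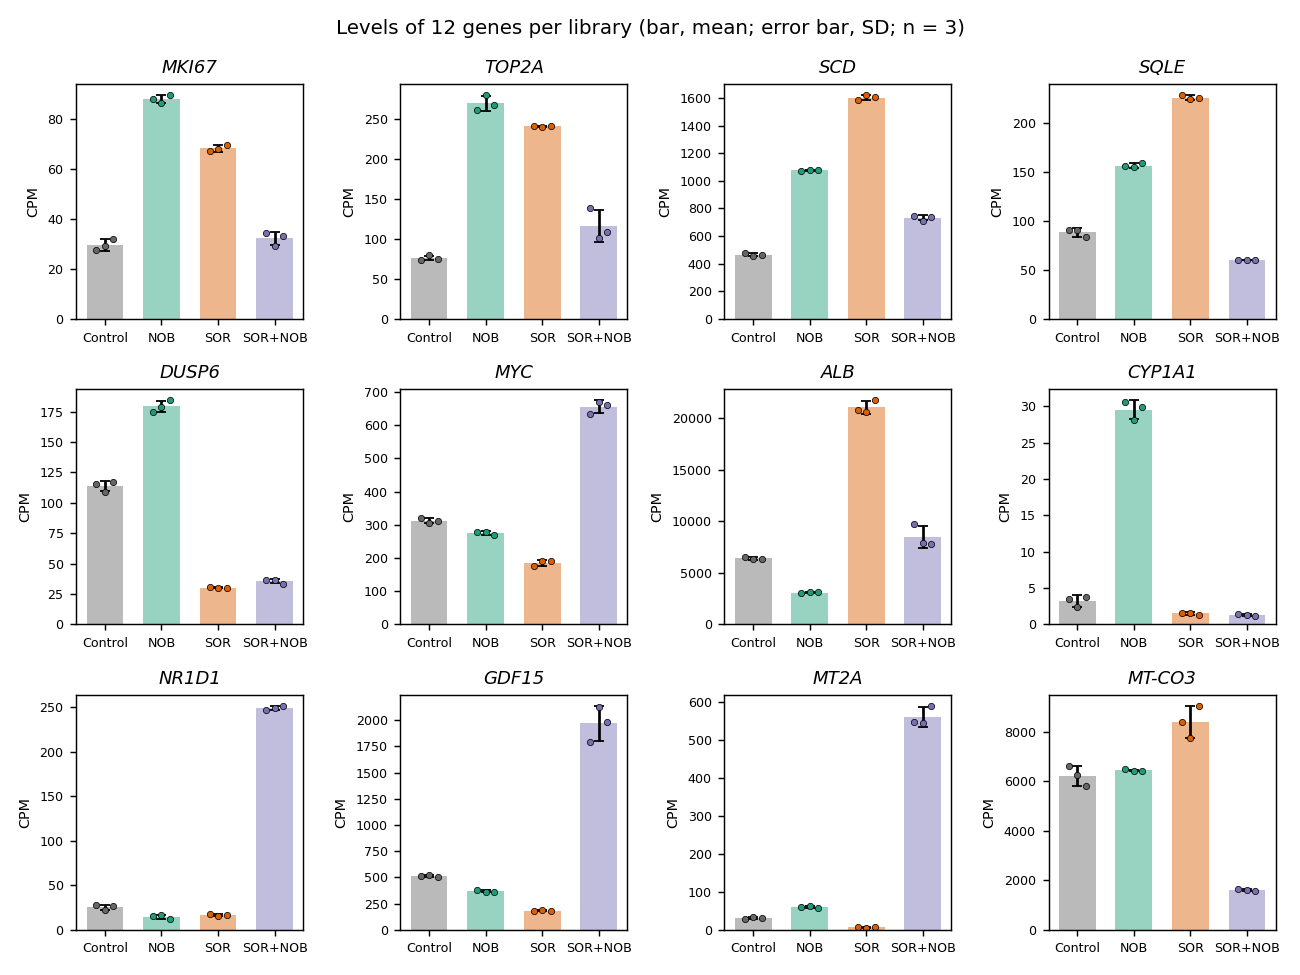
Bars are mean CPM (vertical axes start at 0), error bars the SD and points the 3 libraries of each group, for 12 genes. MYC, NR1D1, GDF15 and MT2A had their highest means in SOR+NOB, MKI67, TOP2A, DUSP6 and CYP1A1 in NOB, and SCD, SQLE, ALB and MT-CO3 in SOR.

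In SOR+NOB against SOR, which measures the addition of nobiletin to sorafenib, the lipid synthesis genes fell, and ERK output and inflammation genes rose. Cholesterol genes fell in 22 of 24 (23 adjusted over the list alone, median -1.25, camera adjusted p = 7.69e-09). The squalene epoxidase SQLE went from 226 ± 2.42 to 59.9 ± 0.214 CPM. Fatty acid and triglyceride synthesis genes fell in 12 of 18 and rose in 4 (16 adjusted over the list alone, median -0.80, adjusted p = 0.00389), DGAT2 at -3.74. Fatty acid oxidation genes fell in 15 of 20 and rose in 2 (17 adjusted over the list alone, median -0.65, adjusted p = 3.87e-04). ERK output genes rose in 14 of 21 and fell in 4 (18 adjusted over the list alone, median 0.88, adjusted p = 0.00160), EGR1 by 1.89 and MYC by 1.82. DUSP6 stayed low, at 36.6, 36.3 and 33.5 CPM in the SOR+NOB libraries. It was at 30.8, 29.8 and 30.3 CPM in SOR and at 115, 109 and 117 CPM in Control. NF-kB and acute inflammation genes rose in 11 of 14 and fell in 1 (12 adjusted over the list alone, median 1.83, adjusted p = 2.44e-04), IRF1 by 2.33 and NFKB2 by 2.03. Bile acid genes fell in 9 of 12 and rose in 1 (10 adjusted over the list alone, median -0.87, adjusted p = 0.00309), with CYP7A1 at 0 counts against 896, at least 308-fold lower. Hepatocyte secreted proteins fell in 21 of 24 and rose in 1 (22 adjusted over the list alone, median -0.99, adjusted p = 3.37e-07, and adjusted p = 0.0514 with an estimated correlation). ALB went from 21066 ± 597 to 8481 ± 1095 CPM.

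Metal response genes rose in 7 of 8 when nobiletin was added to sorafenib (7 adjusted over the list alone, median 6.67, or 5.95 with MT1M at its bound, camera adjusted p = 1.26e-05). MT2A went from 6.68 ± 0.883 to 562 ± 25.3 CPM. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone, median -1.63, adjusted p = 6.05e-07, and adjusted p = 0.174 with an estimated correlation). The mitochondrial rRNA share was 1.94% ± 0.0875 in SOR and 2.91% ± 0.180 in SOR+NOB. Histone genes, whose main transcripts lack a poly(A) tail, rose in 6 of 8 (6 adjusted over the list alone, median 1.56, adjusted p = 0.00352), HIST1H1C by 3.58. DNA replication genes rose in 19 of 24 and fell in 3 (22 adjusted over the list alone, median 0.91, adjusted p = 2.44e-04), CDC45 by 2.23. Mitosis genes fell in 14 of 24 and rose in 2 (16 adjusted over the list alone, median -0.46, adjusted p = 0.00321, and adjusted p = 0.131 with an estimated correlation), MKI67 at -1.09. Endoplasmic reticulum chaperones rose in 17 of 19 (17 adjusted over the list alone, median 0.60, adjusted p = 1.19e-06), DNAJB9 by 1.92. Autophagy and lysosome genes rose in 15 of 23 and fell in 2 (17 adjusted over the list alone, median 0.48, adjusted p = 2.44e-04), the proton pump subunit ATP6V1H by 1.49. Heat shock genes rose in 12 of 16 and fell in 3 (15 adjusted over the list alone, median 0.83, adjusted p = 0.00540, and adjusted p = 0.0540 with an estimated correlation). Glycolysis genes rose in 14 of 22 and fell in 1 (15 adjusted over the list alone, median 0.37, adjusted p = 0.00120, and adjusted p = 0.0771 with an estimated correlation), SLC2A1 by 2.14. GDF15 rose by 3.42, and GSTA1 (-6.05), F13B (-5.97) and OTC (-5.94) had the largest falls among genes with counts in both groups. Reads shared between GSTA1 and its close paralog GSTA2 make their split uncertain.

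In SOR+NOB against NOB, which measures the addition of sorafenib to nobiletin, clock genes rose in 13 of 18 and fell in 2 (15 adjusted over the list alone, median 0.94, camera adjusted p = 0.00136), NR1D1 by 4.09, PER1 by 3.56 and BHLHE40 by 3.09, all repressors within the clock. Mitosis genes fell in 17 of 24 and rose in 1 (18 adjusted over the list alone, median -0.74, adjusted p = 1.88e-04, and adjusted p = 0.0862 with an estimated correlation). MKI67 went from 88.0 ± 1.64 to 32.2 ± 2.66 CPM. DNA replication genes rose in 16 of 24 and fell in 3 (20 adjusted over the list alone, median 0.51, adjusted p = 0.00996, and adjusted p = 0.0862 with an estimated correlation). Metal response genes rose in 7 of 8 (7 adjusted over the list alone, median 3.64, adjusted p = 1.51e-04), and HAMP rose by 6.49 ± 0.15. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone, median -1.38, adjusted p = 5.34e-06, and adjusted p = 0.217 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 14 of 28 and fell in 3 (17 adjusted over the list alone, median 0.22, adjusted p = 0.0218, and adjusted p = 0.311 with an estimated correlation). Histone genes rose in 5 of 8 (5 adjusted over the list alone, median 1.15, adjusted p = 0.02, and adjusted p = 0.0907 with an estimated correlation). Autophagy and lysosome genes rose in 16 of 23 and fell in 3 (19 adjusted over the list alone, median 0.54, adjusted p = 0.00211). Endoplasmic reticulum chaperones fell in 15 of 19 and rose in 1 (16 adjusted over the list alone, median -0.29, adjusted p = 0.00136).

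Cholesterol genes fell in 16 of 24 when sorafenib was added to nobiletin and rose in 2 (18 adjusted over the list alone, median -0.37, camera adjusted p = 0.00136, and adjusted p = 0.0688 with an estimated correlation). Fatty acid synthesis genes fell in 11 of 18 and rose in 3 (15 adjusted over the list alone, median -0.25, adjusted p = 0.0355, and adjusted p = 0.103 with an estimated correlation). Hepatocyte secreted proteins rose in 17 of 24 and fell in 3 (21 adjusted over the list alone, median 0.40, adjusted p = 0.00161, and adjusted p = 0.217 with an estimated correlation), ALB by 1.46. NF-kB genes rose in 8 of 14 and fell in 2 (10 adjusted over the list alone, median 1.61, adjusted p = 0.0121, and adjusted p = 0.137 with an estimated correlation). RELB rose by 2.52 and the NF-kB inhibitor TNFAIP3 by 2.13. p53 targets rose in 13 of 21 and fell in 3 (16 adjusted over the list alone, median 0.58, adjusted p = 0.00308, and adjusted p = 0.155 with an estimated correlation). Heat shock genes rose in 11 of 16 and fell in 3 (15 adjusted over the list alone, median 0.65, adjusted p = 0.00560, and adjusted p = 0.0862 with an estimated correlation). NRF2 targets rose in 13 of 23 and fell in 6 (19 adjusted over the list alone, median 0.39, adjusted p = 0.0434, and adjusted p = 0.342 with an estimated correlation). This call was also lost with the replicate block (adjusted p = 0.0548) and without NOB replicate 3 (0.0546), SOR+NOB replicate 2 (0.0783) or SOR+NOB replicate 3 (0.0549). CYP1A1 fell by 4.53 ± 0.18 on the log2 scale, from 29.6 ± 1.26 to 1.28 ± 0.131 CPM, and DUSP6 had a log2FC of -2.34. SLC30A2 was at least 182-fold higher, and HRH3 had 710 counts against 1 in NOB (779-fold, 95% counting interval 139 to 30820). PPP2R2C (-5.58) and FJX1 (-4.97) had the largest falls.

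The interaction compared the effect of nobiletin with and without sorafenib. In 100 groupings of the 12 libraries, the real one among them, 12 gave 13 or more called lists. The number of list calls below is therefore not beyond what random groupings gave. Mitosis genes had lower values with both compounds than the sum of the single log2 effects in 23 of 24 members (23 adjusted over the list alone, median -1.93, camera adjusted p = 3.81e-13). Cholesterol genes did so in 23 of 24, with 1 higher (24 adjusted over the list alone, median -1.56, adjusted p = 8.26e-12). Fatty acid synthesis genes were lower in 15 of 18 and higher in 1 (16 adjusted over the list alone, median -0.99, adjusted p = 3.49e-06). Fatty acid oxidation genes were lower in 14 of 20, with 5 higher (19 adjusted over the list alone, median -0.50, adjusted p = 0.0374, and adjusted p = 0.0782 with an estimated correlation). All 13 mitochondrially encoded mRNAs were lower than the sum (13 adjusted over the list alone, median -1.97, adjusted p = 1.43e-07, and adjusted p = 0.171 with an estimated correlation). Higher than the sum were metal response genes in 6 of 8 (6 adjusted over the list alone, median 5.17, adjusted p = 1.96e-05) and NF-kB genes in 10 of 14 (10 adjusted over the list alone, median 2.40, adjusted p = 2.86e-06). So were histone genes in 5 of 8 (5 adjusted over the list alone, median 1.75, adjusted p = 0.00338) and ERK output genes in 13 of 21, with 4 lower (17 adjusted over the list alone, median 1.35, adjusted p = 5.66e-04). Heat shock genes were higher in 13 of 16 and lower in 2 (15 adjusted over the list alone, median 1.03, adjusted p = 1.96e-05), and clock genes in 12 of 18 with 4 lower (17 adjusted over the list alone, median 0.85, adjusted p = 0.00651). Autophagy genes were higher in 18 of 23 and lower in 2 (20 adjusted over the list alone, median 0.84, adjusted p = 2.32e-06), and interferon genes in 9 of 16 (9 adjusted over the list alone, median 0.76, adjusted p = 0.00935). Single values of the interaction (log2) were -2.66 for MKI67, -2.88 for TOP2A, -2.34 for SCD, 5.46 for MT2A, 4.73 for NR1D1, 3.89 for GDF15 and 2.00 for MYC. Of the 8908 genes called, 4298 were higher and 4610 lower than the sum, and 9807 were called without SOR+NOB replicate 1.

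Lists called in none of the 6 comparisons were apoptosis regulators, hypoxia response, xenobiotic metabolism, LXR targets and cytosolic ribosomal proteins. In SOR+NOB against Control their camera adjusted p was 0.704, 0.857, 0.287, 0.137 and 0.0548. Their members were not unchanged. In the same order 6, 8, 2, 2 and 14 members were higher and 5, 8, 7, 5 and 0 lower. Those tested numbered 21, 18, 13, 7 and 32 (11, 16, 9, 7 and 14 called when adjusted over the list alone). Of all genes tested, 64.2% were called in that comparison. Markers of other cell types gave no call either. Of the blood and endothelial markers 5 were tested (in SOR+NOB against Control 1 higher and 4 lower, 5 adjusted over the list alone, median -1.46, camera adjusted p = 0.15). Of the fibroblast and of the non-liver epithelial markers 2 each were tested, too few for the list test (medians -1.23 and -0.82). The labels do not say that the replicates are separate cultures, so edgeR and permutation p-values measure only the spread between these libraries, which may be technical. Camera p-values compare a list with other genes at a preset correlation of 0.01, so they rest on the spread between genes too. For mitosis in NOB against Control, camera adjusted p was 9.66e-20 with the preset and 0.00253 with an estimated correlation. The latter kind is printed above only where the call was lost. The strand setting of the counting is not stated, so values of genes that overlap another gene on the opposite strand are uncertain.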

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

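The tests of mitochondrial rRNA, mitochondrial tRNA, nuclear rRNA, histones, MT-ND6, gene position, small nuclear and nucleolar RNA, SLC30A1, markers of other cells, equal totals and the response of replicate 2 were chosen only after the result was seen. So was the sum of the metallothioneins. The tests of SLC39A10, of GC and length and of other splits were set before the values they measure were seen. The differences between the effect of nobiletin with and without sorafenib were singled out because the effects differ between the groups by the interaction test.

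By that test 8908 genes differed in effect (edgeR, adjusted p under 0.05). Median log2 differences of the called lists were 0.85 for the clock, 1.35 for ERK output, -1.56 for cholesterol synthesis, -0.99 for fatty acid synthesis, -0.50 for fatty acid oxidation, -1.97 for mitochondrially encoded genes, -1.93 for mitosis, 5.17 for the metal response, 1.03 for heat shock, 0.76 for interferon response, 2.40 for NF-kB, 0.84 for autophagy and 1.75 for histones. With an estimated correlation between genes the calls of fatty acid oxidation (adjusted p = 0.0782) and of mitochondrially encoded genes (adjusted p = 0.171) were lost. Among called protein-coding genes with a mean of at least 2 CPM, the largest positive differences (log2) were those of HRH3 (9.54), ANKRD33B (8.16), MT1X (6.69), PCLO (6.60), GGT5 (6.46), CYR61 (6.42), HAMP (6.36) and IL11 (6.19). The largest negative differences among them were those of CYP7A1 (-9.78), RBP2 (-8.07), PPP2R2C (-6.51), TIGD3 (-6.15), FGFR2 (-4.95), PGLYRP2 (-4.82), DYSF (-4.19) and UNC93A (-4.15). HRH3, ANKRD33B and CYP7A1 had 0 to 3 counts in at least 1 group, so their fitted values depend on the prior count and are no bounds. SLC30A2, with 498 counts in SOR+NOB and 0 in the other groups, was not called (edgeR adjusted p = 0.9998) because the interaction could not be estimated from groups at 0.

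Other splits of the libraries were run through the same fits. Each comparison of 3 against 3 allows 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes (6536, 7020, 10981, 10785 and 10387 called by edgeR). The highest other split gave 0 adjusted calls, with at most 245, 339, 839, 960 and 1159 genes at an unadjusted p under 0.05 in the other splits (DESeq2 was not run on them). For lists, also 1 of 10 each, the real values were 21, 16, 12, 16 and 16 and the highest others 14, 12, 6, 12 and 8. For any difference among groups 1 of 100 regroupings of the 12 libraries, the real one, gave as many genes (13434, highest other 5528). A random grouping is thus an unlikely source of that count. For the interaction it was also 1 of 100 (8908, highest other 2894). This does not decide the interaction count, because regroupings of all 12 libraries also break up the single effects and place them within groups. For the number of interaction lists, 12 of 100 regroupings gave 13 or more, the highest other being 16, so a random grouping is not excluded.

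In SOR+NOB mitochondrial mRNAs were lower and mitochondrial rRNAs higher than in Control. A loss of mitochondrial RNA of every kind stays open: the smaller log2 fold change of the rRNAs was 0.89, but a change in the capture of RNA without a tail would raise them and could hide a loss. Weaker capture of RNA by its poly(A) tail stays open for the rRNA part, since RNA classes without a tail moved apart. The share of small nuclear and nucleolar RNA was 1.48 times that of Control, which goes with it. So does nuclear rRNA, nearly all of it from 5.8S genes, with 273 to 561 counts per SOR+NOB library and 8 to 24 per Control library (29.8 times the mean share). The histone list had a median of 0.88 without a call (camera adjusted p = 0.099). Against it, 16 of 17 mitochondrial tRNAs were lower, including 4 of the 5 with at least 10 CPM in Control (-2.75 to -1.88). The tRNAs do not settle it, because reads of longer precursors may be counted in these short genes. For the mRNA part the tRNAs also go against it, as does MT-ND6, whose mRNA lacks a tail and was at -1.20, but MT-ND6 decides only if counting used the strand. The correlation of fold change with gene position (Spearman rho -0.20 over 12 heavy-strand genes, permutation p = 0.544) does not decide whether transcription falls off with distance. The mitochondrial rRNA share was also higher with each compound alone, 1.75% in NOB and 1.94% in SOR against 1.36% in Control. The interaction (log2) was 0.05 for MT-RNR2 (edgeR adjusted p = 0.627) and 0.74 for MT-RNR1 (adjusted p = 1.33e-08). In SOR small nuclear and nucleolar RNA took a lower share than in Control (0.00681% against 0.00867%), while nuclear rRNA had 72 counts against 48. An effect of both compounds together on mitochondrial RNA stays open and untested.

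Metal response genes were far higher in SOR+NOB than in every other group. Reads shared among metallothionein copies do not explain SLC30A1, which has no near-identical copy and rose by 1.23 on the log2 scale. SLC30A1 says little of the copies themselves, since it also rose in SOR (0.41), where the summed metallothioneins were at 12.4 ± 1.32 CPM. CPM of metallothionein sums and of markers in this paragraph are per total counts of the library, without TMM scaling. Sharing among the 9 metallothionein genes would only move reads between them. Their sum went from 43.9 ± 4.18 CPM in Control to 1230 ± 26.0 in SOR+NOB, which argues against sharing as the cause of their rise. RNA from other cells is argued against by the 39 markers of other cell types, whose sum changed by -43.8% of the rise of the metallothioneins (from 1019 ± 11.9 to 500 ± 30.4 CPM, most of it LYZ and VIL1, which HepG2 expresses); the 34 markers under 5 CPM in Control, a subset chosen after their values were seen, went from 8.85 ± 0.863 to 4.40 ± 1.38 CPM, -0.375% of that rise. More free zinc or another metal sensed by the cells is a candidate explanation: SLC39A10, a zinc importer lowered by zinc, was at -0.41 ± 0.07. That is weak evidence, since 5475 of 17115 genes were lower and its interaction had edgeR adjusted p = 0.225, and the metal response stays a hypothesis with no metal measured.

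SOR+NOB replicate 1 stood apart from replicates 2 and 3. Its lower depth is argued against as the cause, because with all 3 libraries thinned to 17945656 counts the smaller chi-square per degree of freedom of replicate 1 was still 3.74 times that of replicates 2 and 3 (25.5 and 18.1 against 4.84). A larger or smaller response of the same kind is argued against by the Pearson r of 0.0226 between replicate 1 minus 3 and replicate 2 minus Control. That r covers 9729 genes with a mean log2 CPM above 3. On the first principal component replicate 1 lay further from Control, at 109 against 87.1 and 91.9, so a larger response in part stays open. GC content and transcript length explained 44.5% of the variance of the deviation of replicate 1 over the 9729 genes (Spearman rho with GC -0.70). This lies between the values set for and against them, so a technical difference in GC may account for part of the deviation. The labels give no batch, and a difference of the culture stays untested.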

How the results depend on the processing

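Removal of the GC and length trend was chosen only after the data were seen, and all other alternatives were planned. Lists were rerun only with an estimated correlation, fry, RLE scaling, no filter on low counts, the replicate block and each library left out. Whether the list calls hold with the GC and length trend removed was not tested. Counts of called genes stayed within 1.5 times the main count in every alternative run. With DESeq2 they were 6661, 7152, 11040, 10857, 10482 and 9041 (the 6 comparisons in the report's order), with limma on FPKM and a pseudocount of 1 5820, 6312, 9670, 9511, 9175 and 7885, and with the replicate block 6347, 6816, 10798, 10650, 10212 and 8741 (any difference 13252, lists 21, 15, 12, 16, 15 and 13, overlap of the compounds 2994, r of their effects 0.408, slope 0.395). Leaving out 1 library gave 5463 to 5622 genes for NOB against Control, 5968 to 6252 for SOR against Control, 10160 to 11392, 10049 to 11222 and 9592 to 10905 for SOR+NOB against Control, SOR and NOB, 8280 to 9807 for the interaction and 13133 to 14109 for any difference. The lists then numbered 20 to 22, 16 to 17, 11 to 13, 16 to 18, 15 to 17 and 13 to 14, the overlap of NOB and SOR calls was 2505 to 2590, their r 0.437 to 0.454 and the slope on the sum 0.392 to 0.408. With an estimated correlation, SOR against Control kept 8 lists, SOR+NOB against Control 2 and against NOB 4. Fry, which does not compare a list with other genes, called 29 lists for SOR against Control, 31, 28 and 30 for SOR+NOB against Control, SOR and NOB, and 30 for the interaction, where no filter on low counts called 21; the cause was not tested. FASN in SOR+NOB against Control reversed from -0.27 to 0.15 (adjusted p = 0.0551) with the GC and length trend removed, where the 15 alternatives of this result gave adjusted p of 3.43e-07 to 0.0551; the cause was not tested. Among all called genes, the same removal left 24 of SOR+NOB against Control and 2 of SOR+NOB against SOR called with the opposite sign, and 0 in the other 4 comparisons. Over 2304 alternatives of lists, 2131 kept their side of the threshold, 53 lost the call, 120 gained one and 0 called results reversed. Over 9807 of named genes these numbers were 9715, 60, 31 and 1. The same direction was required only of results called in the main fit (94 of 192 for lists, 588 of 628 for genes). An uncalled result that changed direction was not counted as reversed. RLE scaling moved the median of all genes in SOR+NOB against Control by -0.02 log2, the largest shift of the 6 comparisons. Both scalings assume that rises and falls balance over most genes, so their agreement cannot show whether total RNA per cell changed. Depth limits the genes with few counts, and the simulated test recovered 54% of 1.5-fold changes, with far fewer genes changed than were called in the data.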

Other observations

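The gene family below was chosen only after its values were seen, so no p-value is given and its fall is a hypothesis. Of 497 tested members of the C2H2 zinc finger family, 229 fell and 105 rose in SOR+NOB against Control, with a median log2 fold change of -0.30 (-0.17 with the GC and length trend removed). Against SOR 239 fell and 89 rose (median -0.35, and -0.27 with the trend removed). With NOB alone the median was -0.05 and with SOR alone 0.02, and the interaction had a median of -0.27 (-0.21 with the trend removed).

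Across genes, which are not independent replicates, the log2 fold change of SOR+NOB against Control had a Spearman rho of 0.156 with the number of exons and -0.106 with GC content.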
